A study of Caenorhabditis elegans with 14 samples.

How the data were processed

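Small RNAs of Caenorhabditis elegans were sequenced in 14 libraries, 6 untreated and 8 treated with TDP2, from synchronised late young adults grown at 20 °C on OP50 bacteria. Per the labels' protocols, the RNA was either made into a library directly or first dephosphorylated and then treated with Tobacco Decapping plus 2 (TDP2), an enzyme that removes 5′ caps and leaves a ligatable end; RNA of 17 to 30 nucleotides was gel-purified. An untreated library captures RNAs with a 5′ monophosphate, such as mature piRNAs and microRNAs. In a TDP2 library the dephosphorylation should take such ends away, while capped RNAs such as piRNA precursors (pre-piRNAs) become clonable. The libraries did not all follow this: microRNAs took a larger share with TDP2 in control, as did mature piRNA features in prg-1. Antisense small RNAs of RNA-dependent RNA polymerases start with a triphosphate, which dephosphorylation should also remove; they rose after TDP2 here, and why was not tested. The groups were the control strain, tofu-6, pics-1, erh-2, prg-1 and tost-1 mutants, taken from the sample labels. The 4 TDP2 libraries of tofu-6 came from 4 different alleles (it20, ust94, ust95 and yt2, replicates 1 to 4), and every other group had 1 library. The replicates were therefore different strains, nothing in the labels says that they were separate cultures, and p-values measure the spread between these libraries only.

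The authors deposited, for each library, a table of whole-number read counts per transcript or piRNA on both strands and a table of the same counts summed by class and strand. The alignment used Bowtie2, per the submitters' processing notes; its version, the genome build, the handling of reads with several matches and the counting tool are not given in the sources used here. Reads of near-identical copies (histone, heat shock, msp and microRNA genes) may have been split or counted for each copy, so single members of such families are uncertain. Features called antisense could overlap another gene, and the ncRNA antisense counts were a case of this: 419 ncRNA genes lay opposite structural RNA genes and held 90.1% to 98.8% of those reads. Precursor piRNA features may likewise hold reads of an overlapping gene, which was not tested, so precursor counts and shares may include such reads.

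The transcript counts were summed here per gene and strand. Gene names and coordinates came from the WBcel235 annotation, in which 44845 of 45503 gene identifiers were found; 229 genes fell in more than 1 class. Each class table was compared with the sums of the feature table: 13 libraries were equal in all 26 values once the strands of 7 rRNA features were exchanged, which the deposited class tables also do. The class table the authors deposited for untreated tofu-6(ust94) held RPM instead of counts: its values were the counts divided by 9884492 reads, against 9884323 reads outside rRNA. The feature tables were used for all values, with the 7 rRNA features turned round. The authors list each piRNA as a pre-piRNA and a mature piRNA feature; 15365 further piRNA locus entries held 1 read over all libraries. Left out were 3 entries with no class, which held 3 to 27 reads per library. The totals of assigned reads ran from 6918136 to 13469619 per library. The tofu-6 TDP2 libraries differed far beyond counting error (chi-square per degree of freedom 71.1 to 196), so no library was counted as a copy of another.

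Shares of assigned reads by class were given with exact Clopper-Pearson 95% intervals; all intervals cover counting error only, since reads were not counted as molecules. For the TDP2 libraries, edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM) was fitted to all 8 libraries with 5 genotype groups and 3 residual degrees of freedom, all from the tofu-6 alleles; a genotype with 1 library is assumed to vary as these alleles do. Levels in TDP2 libraries are given as CPM, counts scaled to the TMM-adjusted library size, and in untreated libraries as RPM, scaled to the assigned reads. Features needed 10 reads in a library and 30 over the fit, which left 22372. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05; the median trended biological coefficient of variation was 0.561 and the prior degrees of freedom were infinite. Each test therefore used a spread pooled over features, and a feature's own spread between alleles had no weight in it. A feature with 1 extreme allele could pass. The effect of TDP2 was fitted on 10 libraries of 5 strains with strain as a block, which left 4 residual degrees of freedom and 21673 features; here the pairing comes from the strain name in the labels. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated one, over lists with 3 or more tested members. Each untreated mutant was compared with the untreated control, 1 library against 1, so no p-value was computed. Ratios of RPM were given with exact counting intervals for features with at least 100 reads in 1 of the 2 libraries, and changes of at least 4-fold were counted (0.5 reads added). Each list's median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean expression. Random lists take no account of members that move together or share reads. Such a list reaches an extreme percentile more easily, so the percentiles are not p-values. Where a group had no read, the fold was computed against 3 reads over the group and is given as a lower bound.

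The following choices were made before the data were examined: groups, tests, the other settings to be tried, the lists and the rule for named features. The lists were piRNA loci, microRNA genes, the let-7, mir-35, mir-51, mir-58 and lin-4 families, histone, rRNA and other structural RNA genes, piRNA pathway genes, 22G pathway genes, WAGO-class examples, ERGO-1 26G targets, germline and oocyte genes, sperm genes, somatic genes, mitochondrial genes and transposon features. The lin-4 family and the transposon features had fewer than 3 tested members and gave no result. No read or no entry was found for mir-48, mir-1834, mir-58.1, tofu-3, cde-1, rde-3, C40A11.10, E01G4.7, F39E9.7, H16D19.4 and T08B6.2; pics-1 is named pid-3 in the annotation. The rule named the 6 piRNA loci with most reads in the control, up to 4 members of each list with most reads, and the 5 largest rises and 5 largest falls past the threshold with at least 100 reads (for tofu-6, with all 4 alleles on the same side of control), plus the mutated genes. That rule covers 628 tested features over the 5 TDP2 contrasts. Of these, 114 are printed, chosen after their values were seen and mostly because they passed the test, so the printed features are not a fair sample of the rule. Features are named with the strand of their reads, and a WormBase identifier follows a symbol shared by several genes.

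Other settings fixed then were DESeq2 1.42.0 size factors, scaling to microRNA reads, other filters, the DESeq2 Wald test, each tofu-6 allele or strain pair left out, a fit of 10 libraries with genotype plus library type, no strain block, other denominators of the shares, camera without piRNA loci, and other scalings and a minimum of 20 reads for the untreated libraries. Scaling to microRNA reads holds the summed microRNA reads level, so the medians of microRNA genes under it cannot show a change of that class. Chosen after seeing the data were fits without features antisense to piRNA loci, fits without rRNA features, and shares over the 521 mature piRNA features with at least 10 reads in the untreated control.

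The code was tested on simulated counts. The values below come from the second of 2 runs with different random seeds; the seed was changed because its digits matched a printed count, and recovery was similar in both. With 67, 67 and 66 features changed 4-, 16- and 64-fold, the tofu-6 contrast recovered 9%, 46.3% and 95.5% of them with 5 false calls among 21414 features. The pics-1 contrast recovered 1.5%, 10.4% and 56.1% (1 false call, 21379 features), the erh-2 contrast 0%, 9% and 63.6% (1 false call, 21432 features), and the prg-1 contrast 1.5%, 7.5% and 51.5% (5 false calls, 21456 features). The contrast of TDP2 against untreated recovered 86.6%, 100% and 100% (3 false calls, 20106 features). In the tofu-6 camera step on 21425 features, the 1 list shifted 4-fold was called and 0 of the other lists, with either correlation. Simulated features were drawn independently from a pooled composition, without correlated genes or class-wide differences between libraries. These runs therefore cannot show how many false feature or list calls such differences cause in the real libraries. For untreated tofu-6(ust94) on 3786 features, 200 of 200 features lowered or raised 8-fold were found when their simulated reads lay between 300 and 5000, with the shifted list at percentile 0 and an unshifted one at 21.6. When changed features were drawn from all with at least 1000 reads, 100 of 200 were found (percentiles 0 and 31.8): those features held 81.5% of the reads, and scaling to the total moved the unchanged features' median log2 ratio to −1.27. R 4.3.3, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.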

Results

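Small RNAs of 17 to 30 nucleotides were sequenced from late young adult worms of the control strain and of 5 mutants, in 6 untreated and 8 TDP2 libraries. The series title names the PICS complex, piRNA maturation and chromosome segregation. TOFU-6, PICS-1 (annotated as PID-3), ERH-2 and TOST-1 were mutated one at a time, as was PRG-1, the Piwi protein that binds mature piRNAs. The untreated libraries held 1 each of control, tofu-6(ust94), pics-1, erh-2, prg-1 and tost-1. The TDP2 libraries held 1 each of control, pics-1, erh-2 and prg-1 and 4 of tofu-6, each from another allele; there was no tost-1 TDP2 library. Assigned reads came to 7070853 in untreated control, 11777844 in tofu-6(ust94), 10555247 in pics-1, 8363650 in erh-2, 10151842 in prg-1 and 6918136 in tost-1. In the TDP2 libraries they came to 9310418 in control, 8789847, 8303487, 9185339 and 8154524 in tofu-6 it20, ust94, ust95 and yt2, 7928250 in pics-1, 13469619 in erh-2 and 8671475 in prg-1. Structural RNA took most reads of nearly every library: the rest made up 15.9% in untreated control and 34.4% in untreated tofu-6(ust94), and 17.9% (prg-1) to 50.7% (pics-1) in the TDP2 libraries. Apart from the tofu-6 TDP2 libraries no group had a replicate.

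The mutated genes themselves all kept reads in the strain named after them, and no library had a count of 0 there. In the TDP2 libraries tofu-6 had 118 sense reads in control and 156, 15, 73 and 130 in the 4 tofu-6 alleles (log2 change −0.31 ± 0.92 SE, adjusted p = 0.900). Reads sense to pid-3 numbered 52 in control and 12 in pics-1 (−2.22 ± 1.30, adjusted p = 1), and reads sense to erh-2 numbered 53 in control and 78 in erh-2 (0.46 ± 1.20, adjusted p = 0.853). Reads antisense to erh-2 numbered 63 and 4 (−4.02 ± 1.44, adjusted p = 0.281), and prg-1 had 201 sense reads in control and 103 in prg-1 (−0.42 ± 1.18, adjusted p = 1). In the untreated libraries the ratio of sense RPM, mutant to control, was 0.183 for tofu-6 (95% counting interval 0.102 to 0.315; 18 and 59 reads) and 0.290 for pid-3 (0.151 to 0.534; 16 and 37 reads). It was 1.31 for erh-2 (0.530 to 3.44; 14 and 9 reads), 0.741 for prg-1 (0.609 to 0.902; 216 and 203 reads) and 0.239 for tost-1 (0.0884 to 0.554; 7 and 30 reads). The deposited counts are per gene, so these values cannot show whether a deleted part of a gene had reads.

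Mature piRNAs, the guide RNAs of PRG-1, were depleted in the untreated prg-1 library and less abundant in tofu-6, pics-1 and erh-2 than in control, while tost-1 had more of them. They made up 0.403% of the assigned reads in untreated control, 0.281% in tofu-6(ust94), 0.120% in pics-1, 0.229% in erh-2, 0.00237% in prg-1 (241 reads) and 0.597% in tost-1. The ratios to control were 0.696 (0.685 to 0.707), 0.299 (0.292 to 0.305), 0.567 (0.556 to 0.577), 0.00589 (0.00516 to 0.00668) and 1.48 (1.458 to 1.502). Per microRNA read the ratios were 0.207, 0.116, 0.2501, 0.00390 and 1.51, and among non-structural reads those of tofu-6, pics-1 and erh-2 were 0.321, 0.159 and 0.326. Of the 6 loci with most reads in untreated control, mature_piR-cel-5504 stood at 0.206, 0.229, 0.482, 0.00400 and 1.32 of control in the same order of mutants, and mature_piR-cel-5107 at 0.291, 0.163, 0.290, 0.00329 and 1.31. For mature_piR-cel-4375 the ratios were 0.555, 0.422, 0.868, 0.00299 and 1.83, and for mature_piR-cel-6009 they were 0.419, 0.202, 0.443, 0.00141 and 1.55. Single loci did not all move together: mature_piR-cel-1793 had ratios of 1.89 in tofu-6(ust94) and 1.53 in erh-2 against 0.525 in pics-1, and mature_piR-cel-3421 had 0.910, 0.985 and 0.479.

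In the TDP2 libraries mature piRNAs made up 0.171% of assigned reads in control, 0.0612% ± 0.0230 in tofu-6 (SD, n = 4 alleles, 0.0427 to 0.0946), 0.0293% in pics-1, 0.0380% in erh-2 and 0.0259% in prg-1. The ratios to control were 0.358, 0.171, 0.222 and 0.152. Scaled per microRNA read the direction turned for tofu-6 (1.17; 1.71, 1.01, 1.13 and 0.813 in the 4 alleles) and erh-2 (2.29), and the ratios were 0.381 in pics-1 and 0.838 in prg-1. Over the 521 mature piRNA features with 10 or more reads in untreated control, a set chosen after seeing the data, the ratios per microRNA read were 0.888, 0.684, 1.03 and 0.668 in the 4 alleles, 0.137 in pics-1, 0.647 in erh-2 and 0.0978 in prg-1, so there only ust95 lay above control. These features were kept by their reads in control, which can pull ratios to control down, so they do not set the reversal aside. MicroRNAs themselves took 8.35% of reads in control, 2.70% ± 1.10 in tofu-6 and 0.810% in erh-2. Precursor piRNAs made up 0.177% in control, 0.234% ± 0.0739 in tofu-6 (0.825 to 1.84 times control over the alleles), 0.319% in pics-1, 0.217% in erh-2 and 0.181% in prg-1. The number of precursor reads per mature piRNA read needs no scaling, but microRNAs, which carry a monophosphate as mature piRNAs do, also stood low in the mutants, at 0.0970 (erh-2) to 0.491 (ust95) of control. Control was the odd library there: its microRNA share went from 4.01% untreated to 8.35% with TDP2, against 13.5% to 2.06% in tofu-6(ust94), 10.37% to 3.75% in pics-1, 9.09% to 0.810% in erh-2 and 6.05% to 1.51% in prg-1. The number of precursor reads per mature read was 1.03 in control, 4.02 ± 1.35 in tofu-6 (5.70, 3.41, 2.55 and 4.41 by allele), 10.9 in pics-1, 5.72 in erh-2 and 6.99 in prg-1. All 4 tofu-6 alleles lay above control by more than the SD between them. In the untreated libraries, where few precursors were captured, this number was 0.0287 in control, 0.108 in tofu-6(ust94), 0.201 in pics-1, 0.0917 in erh-2, 5.25 in prg-1 and 0.0207 in tost-1. All precursor reads were also divided by the mature reads of the 521 features alone. This gave 1.93 in control TDP2, 5.21 to 20.4 in tofu-6, 56.6 in pics-1, 37.8 in erh-2 and 111 in prg-1. The precursor reads were not limited to the same loci. Because the 521 features were kept by their reads in control, these numbers can be too high in the mutants. These features held 8541 of the 15916 mature piRNA reads in control TDP2 and 141 of the 2250 in prg-1 TDP2. The TDP2 shares and ratios over all mature features thus include many reads at features little seen in untreated control.

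**Figure D1:**
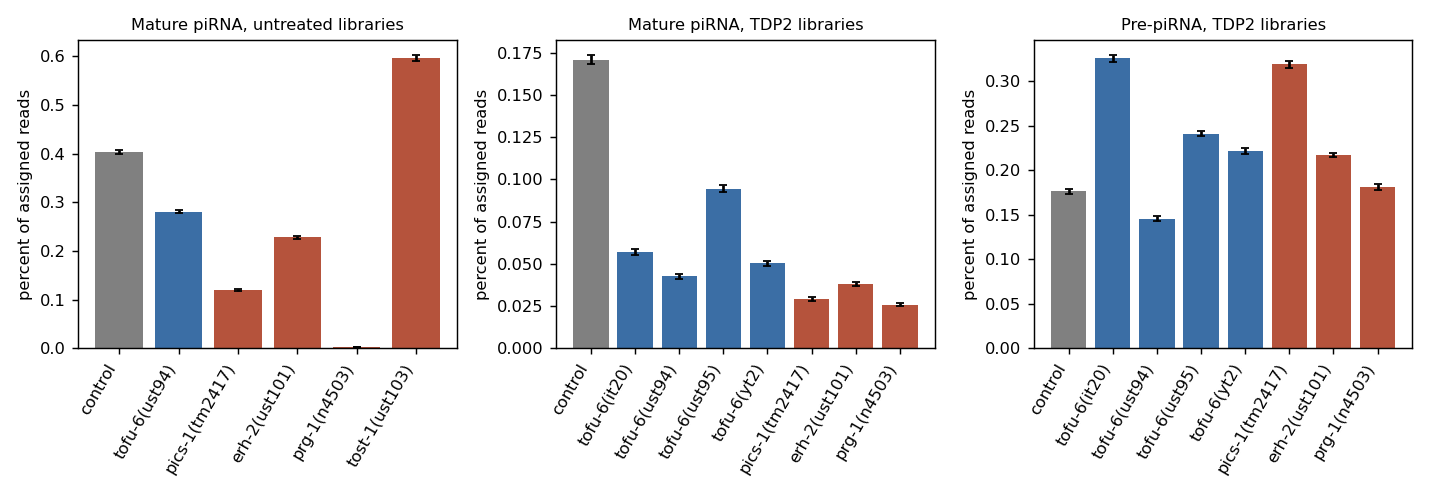
Bars give mature piRNA reads in the untreated libraries, mature piRNA reads in the TDP2 libraries and pre-piRNA reads in the TDP2 libraries, each as a percentage of assigned reads per library with exact 95% intervals for counting error. Mature piRNAs made up 0.403% of reads in untreated control and 0.00237% in untreated prg-1, and among TDP2 libraries control lies highest at 0.171%, an order that turns for tofu-6 (1.17 times control) and erh-2 (2.29 times) when all mature features are counted per microRNA read.

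TDP2 treatment was compared with no treatment across 5 strains, to see which RNAs the enzyme made clonable. Precursor piRNAs and antisense small RNAs rose, and mature piRNAs and microRNAs fell: of 21673 features 9300 were higher and 2694 lower after TDP2. Not every pair followed: as shares of assigned reads, microRNAs went up in the control pair (4.01% to 8.35%) and mature piRNA features in the prg-1 pair (0.00237% to 0.0259%). Of the 2250 such reads in prg-1 TDP2 648 lay on mature_piR-cel-15879. Only 141 lay on the 521 features with 10 or more reads in untreated control, whose share went from 0.000887% to 0.00163%. The rise was therefore mostly at features little seen in untreated control. Of 386 precursor piRNA features 343 rose and 7 fell (median log2 change 5.38), of 7971 features antisense to protein-coding genes 7214 rose and 48 fell (3.87), and of 670 mature piRNA features 40 rose and 489 fell (−3.70). Among the precursors, pre_piR-cel-5504 rose by 6.38 ± 0.77 (adjusted p = 0.000149) and pre_piR-cel-1793 by 5.03 ± 0.82 (adjusted p = 0.000483), each in 5 of 5 pairs. The mature_piR-cel-4375 feature fell from a mean of 85.1 to 1.11 CPM (log2 −6.54 ± 0.74, adjusted p = 0.000132, lower in every pair). Of the others, mature_piR-cel-5107 changed by −6.48 ± 0.68 (adjusted p = 0.000103), and mature_piR-cel-5504, mature_piR-cel-6009, mature_piR-cel-1793 and mature_piR-cel-3421 by −4.19, −4.85, −4.73 and −4.78. Antisense reads rose at 17 of 17 22G pathway genes (4.10), 30 of 30 germline and oocyte genes (4.12) and 16 of 16 piRNA pathway genes (4.01). They rose at 69 of 69 histone genes (4.12), 9 of 9 WAGO-class genes (4.52), 14 of 15 ERGO-1 26G targets (3.07) and 25 of 25 somatic genes (4.49). Of 26 sperm genes 1 rose antisense and 1 fell, with a list median of −0.13 (1.43 when scaled to microRNA reads). Among 148 microRNA genes 10 rose and 93 fell (−2.25, and −0.13 when scaled to microRNA reads), with mir-355 (−5.71 ± 0.71, adjusted p = 0.000160) and mir-59 (−5.69 ± 0.68, adjusted p = 0.000149) among the largest falls. The −0.13 follows from that scaling, which holds the summed microRNA reads level. Of 82 snRNA features, capped in the cell, 56 rose and 0 fell (3.76), and the mitochondrial transcript MTCE.19 changed by −6.05 ± 0.46 (adjusted p = 2.4e-05). The largest rises were Y61B8A.6 sense (10.15 ± 0.57, adjusted p = 1.7e-05), K06C4.19 sense (0 to 17.3 CPM, adjusted p = 0.000139) and wdr-62 antisense (0 to 3.75, adjusted p = 0.000847), each higher in 5 of 5 pairs. Antisense reads at aly-1 and Y41D4B.36 passed the test (adjusted p = 0.00225 and 0.00119) and were higher in 3 and 2 of 5 pairs. The largest falls outside these classes were K08E3.13 antisense (−6.08 ± 0.44, adjusted p = 2.4e-05) and F49E12.14 antisense (−5.62 ± 0.58, adjusted p = 9.9e-05). The median of all features was 0.68, 2.92 when scaled to microRNA reads and 0.79 with DESeq2 size factors. With the microRNA scaling 13412 features were higher and 376 lower, and the medians of mitochondrial genes turned from −2.20 to 0.03, of tRNA from −1.33 to 0.86 and of sense reads at protein-coding genes from −0.33 to 1.93. Without the prg-1 pair 8382 were higher and 4030 lower, with a median of 0.28.

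In the tofu-6 TDP2 libraries 9 of 264 mature piRNA features, 2 of 129 microRNA genes and the collagens col-74 and col-165 fell, and antisense reads rose at 8 of 70 histone genes. Of 22372 features 20 rose and 39 fell, with a median of all features of 0.14. The mature_piR-cel-4817 feature had a mean of 2.59 ± 2.73 CPM (SD, n = 4) against 51.8 in control, below control in every allele (log2 −4.30 ± 0.81, adjusted p = 0.000516), and mature_piR-cel-3975 stood at −2.24 ± 0.83 (adjusted p = 0.462). Of 264 mature piRNA features 1 rose and 9 fell, or 7 and 57 adjusted over the list alone (median −1.72, −0.00 when scaled to microRNA reads). Of 507 precursor features 0 passed either way by edgeR, with or without the adjustment over the list alone (median 0.66), and pre_piR-cel-18932 stood at 0.05 ± 0.96 (adjusted p = 0.986). Sense reads at histone genes, whose replication-dependent copies encode chromatin proteins, had 0 of 71 members past the test over all features and 48 lower adjusted over the list alone (median −2.20). Among them his-18 stood at −2.83 (adjusted p = 0.143) and his-47 (WBGene00001921) at −3.14 (adjusted p = 0.0659). Antisense reads rose at 8 of 70 histone genes, or 14 adjusted over the list alone (median 1.20). They included his-30 (WBGene00001904) at 6.73 ± 1.62 (adjusted p = 0.0236), his-12 (WBGene00001886) at 5.79 ± 1.47 (adjusted p = 0.0393) and his-47 (WBGene00001931) at 5.70 ± 1.41 (adjusted p = 0.0303), above control in 4 of 4 alleles. The yt2 library decided the size of the last: it had 316 CPM there, against 3.78 to 33.2 in the other alleles. The other named copy, his-47 (WBGene00001921), stood at 5.83 ± 1.42 (adjusted p = 0.0248), above control in 3 of 4 alleles, and at 2.44 without yt2. At his-24 antisense reads numbered 2531 in control and 3823, 1636, 3948 and 5970 in it20, ust94, ust95 and yt2. The alleles thus differed at other histone genes too, and ust94 did not rise at his-24. Camera placed the sense list lower (adjusted p = 4.9e-41, and 0.222 with an estimated correlation) and the antisense list higher (6.6e-11, and 0.588 with an estimated correlation).

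The cuticle collagens col-74 (II 5830374–5832022) and col-165 (X 4353618–4354852) fell in tofu-6, from 59.5 to 3.85 and from 117 to 7.62 CPM sense (log2 −3.93 ± 0.81 and −3.93 ± 0.79, adjusted p = 0.00195 and 0.00139). These were the 2 of 116 somatic genes that fell sense (2 also adjusted over the list alone; median −0.22, 1.41 when scaled to microRNA reads). The alleles differed in size: in it20, ust94, ust95 and yt2 col-74 had 30, 7, 105 and 11 sense reads, against 574 in control. At col-165 they had 18, 48, 207 and 21, against 1126, so ust95 kept the most at both. Y37A1B.7 sense (−3.90 ± 0.87, adjusted p = 0.00900), Y48B6A.10 antisense (−3.94 ± 0.83, adjusted p = 0.00287) and mir-8199 (−3.81 ± 0.86, adjusted p = 0.0101) fell as well. Antisense reads at unc-87 (I 6761221–6767797), which encodes a muscle protein, passed the test at 8.48 ± 1.68 (adjusted p = 0.00139), with 313 CPM in yt2 against 0.726 to 0.929 in the other alleles and 0.207 in control. Those at the aquaporin gene aqp-7 were at least 16.8-fold higher (adjusted p = 0.0393). Of 129 microRNA genes 2 fell, or 12 adjusted over the list alone (median −1.21, 0.56 when scaled to microRNA reads), while mir-35 stood at −2.16 (adjusted p = 0.619) and mir-58 at −1.95 (adjusted p = 0.791). The mir-35 family of embryos and oocytes had 6 of 8 members and the mir-51 family 5 of 6 lower adjusted over the list alone, and 0 over all features (medians −2.09 and −2.16). Their camera adjusted p was 5.2e-08 and 1.1e-06, and 0.287 and 0.222 with an estimated correlation. The mir-58 family had 0 of 5 past the test, or 1 lower adjusted over the list alone (median −0.48, 1.04 scaled to microRNA reads), and the let-7 family 0 of 6 (median −0.49, 1.24 scaled to microRNA reads, camera adjusted p = 0.204). In the untreated libraries the microRNA share stood above control instead, at 3.37 times in tofu-6(ust94), 2.58 in pics-1, 2.27 in erh-2 and 1.51 in prg-1. With TDP2 the share rose in control and fell in these mutants. Lower microRNA values against control TDP2, here and below, therefore cannot be read as a loss of microRNAs in the mutants.

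Most other lists had no member past the test in tofu-6 by edgeR. WAGO-class genes, targets of the 22G-RNAs that WAGO proteins carry, stood at a median of −0.17 antisense (1.57 scaled to microRNA reads; camera adjusted p = 0.398) and 0.13 sense (1 of 7 higher adjusted over the list alone; 0.329). Antisense reads at bath-45 stood at 0.07 ± 1.00 (adjusted p = 0.982; −0.37 without yt2) and at the ERGO-1 26G target E01G4.5 at −1.21 (adjusted p = 0.797). ERGO-1 26G targets had 1 of 14 lower sense, or 4 adjusted over the list alone (median −0.78, 0.91 scaled to microRNA reads; camera adjusted p = 0.00112, 0.368 with an estimated correlation). Antisense they had 0 of 15 (−0.32, 1.39 scaled to microRNA reads; adjusted p = 0.0885). Sperm genes had 0 of 41 sense past the test, or 1 lower adjusted over the list alone (median −1.27, 0.13 scaled to microRNA reads; camera adjusted p = 3.5e-12, 0.588 with an estimated correlation), among them smz-1 at −2.92 (adjusted p = 0.0894). Together they held 195 RPM in control and 22.8, 29.9 and 17.9 in it20, ust94 and yt2, but 241 in ust95. Sense medians lay above 0 for germline and oocyte genes (1.10), 22G pathway genes (1.15) and piRNA pathway genes (0.88), at camera adjusted p = 5.4e-06, 0.000142 and 0.00695, each 0.627 with an estimated correlation. Their antisense medians were −0.77, −0.71 and −0.47, which turned to 1.02, 1.07 and 1.25 scaled to microRNA reads (camera adjusted p = 0.000230, 0.00655 and 0.0271; 0.649, 0.656 and 0.668 with an estimated correlation). Antisense reads at sperm genes had a median of −1.07 (0.48 scaled to microRNA reads; 4.4e-05, 0.627 with an estimated correlation), at somatic genes 0.39 (0.610) and at rRNA genes 1.56 (4.8e-06, 0.588 with an estimated correlation). Sense rRNA had a median of −0.14 (1.87 scaled to microRNA reads; 0.848) and mitochondrial genes 0.14 (0.324). Other structural RNA had 1 of 775 lower (median −0.70, 1.08 scaled to microRNA reads; 4.3e-08, 0.222 with an estimated correlation). The remaining camera calls in tofu-6 were mature piRNAs (4.5e-23, 0.222 with an estimated correlation), precursors (0.0192, 0.782), microRNAs (6.7e-19, 0.222), somatic sense reads (0.00238, 0.649) and the mir-58 family (0.0311, 0.368). Over the 5 contrasts 20, 20, 20, 18 and 14 of 27 lists were called with the preset correlation and 0 with the estimated one.

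The tofu-6 calls depended on the scaling and on single libraries. With DESeq2 size factors, or with rRNA features left out, 0 features passed by edgeR (898 and 982 at an unadjusted p under 0.05, 1256 in the fit above); the DESeq2 Wald test called 9, with 0 of the 12 named calls among them. Without it20 4 passed, without ust94 20, without ust95 24 and without yt2 101, and none of the 12 features named above as past the test remained without it20. The fit of 10 libraries, with ust94 as its only tofu-6 allele, kept 0 of the 12 named calls. It reversed 2 of them, antisense reads at his-47 (WBGene00001921) and his-12 (WBGene00001886). Scaled to microRNA reads 6 rose and 0 fell, and the median of all features moved to 1.88.

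**Figure D2:**
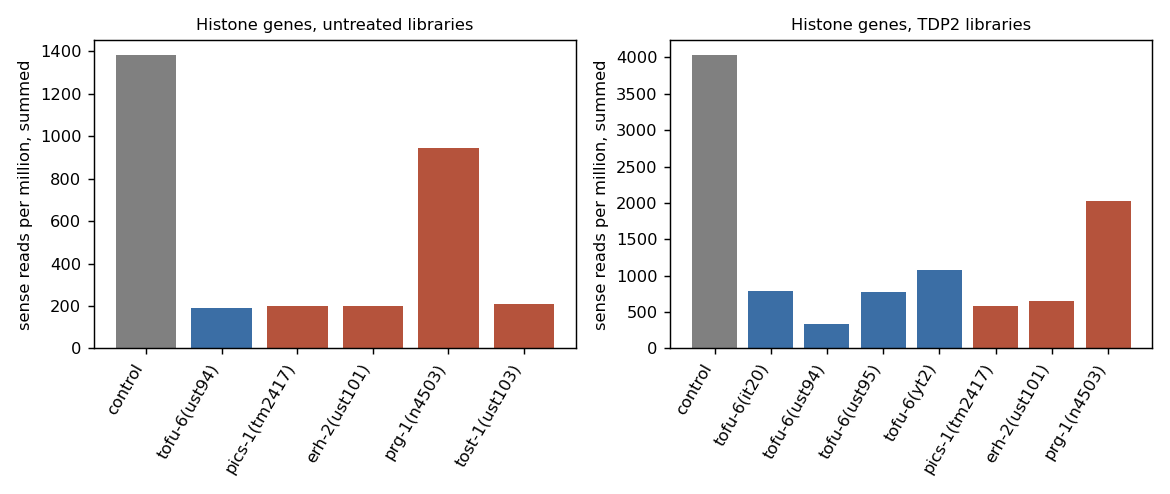
Summed sense reads of the histone genes, as RPM of assigned reads, are drawn for each untreated and each TDP2 library. In untreated libraries control held 1382 and prg-1 943, against 191 to 210 in tofu-6, pics-1, erh-2 and tost-1.

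In the pics-1 TDP2 library fewer features passed the test, and sense reads of col-165, col-74 and cut-2 were among those that fell. Of 22372 features 4 rose and 8 fell (median of all −0.02). The collagens col-165 and col-74 fell (log2 −10.07 ± 1.84 and −9.10 ± 1.81, adjusted p = 0.000336 and 0.00237), with 0.0953 CPM each in pics-1. The cuticulin gene cut-2 (V 13414949–13416064) fell as well (−7.11 ± 1.57, adjusted p = 0.0141). So did Y102A11A.5 sense (−6.22 ± 1.48, adjusted p = 0.0485). Antisense reads at ZK262.9 were at least 194-fold lower (adjusted p = 0.000713) and those at C42D4.19 at least 49.6-fold higher (adjusted p = 0.0250). Somatic genes had 2 of 116 lower sense, or 20 adjusted over the list alone (median −1.97, camera adjusted p = 5.4e-19, 0.306 with an estimated correlation).

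Mature piRNAs had 0 of 264 past the test in pics-1, or 1 higher and 71 lower adjusted over the list alone (median −4.08, −3.12 with features without reads at their bound). Named members stood at −4.59 (mature_piR-cel-3975, adjusted p = 0.188) and −5.26 (mature_piR-cel-4817, adjusted p = 0.121). Histone genes had 0 of 71 past the test sense, or 56 lower adjusted over the list alone (median −3.18; his-47 (WBGene00001921) at −3.53, adjusted p = 0.556). Sperm genes, which include major sperm proteins, had 0 of 41 past the test sense, or 24 lower adjusted over the list alone (median −4.76, −3.75 with bounds), with msp-77 at −5.40 (adjusted p = 0.132) and smz-1 at −5.07 (adjusted p = 0.139). Camera called these 3 lists lower (2.3e-44, 4.2e-48 and 2.9e-34, and 0.222, 0.263 and 0.306 with an estimated correlation). Histone antisense reads had a median of 1.85 (8.6e-24, 0.356 with an estimated correlation) and microRNA genes of −1.07 (0.44 scaled to microRNA reads; 6.4e-07, 0.395 with an estimated correlation), each with 0 members past the test. At WAGO-class genes 0 of 9 passed antisense (median 0.44), with bath-45 at 1.08 ± 1.28 (adjusted p = 1). By edgeR 1174 features had an unadjusted p under 0.05. With DESeq2 size factors or without rRNA features 0 passed (652 and 740 unadjusted), without it20 2, ust94 7, ust95 4 and yt2 45. The Wald test called 13, among them 5 of the 6 named calls, and 5 features passed scaled to microRNA reads (median of all features 1.47, 0.35 with DESeq2 size factors). None of the 6 named calls remained without it20.

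In the erh-2 TDP2 library the 5 largest rises included hsp-70 and 3 hsp-16 genes, and 4 of 41 sperm genes fell. Of 22372 features 13 rose and 25 fell (median of all −0.09). Sense reads of hsp-70 (I 9320325–9322519), an inducible chaperone, were at least 60.6-fold higher (adjusted p = 0.00943). The small heat shock gene hsp-16.2 rose from 0.104 to 20.99 CPM (log2 7.48 ± 1.74, adjusted p = 0.0226), F44E5.5 from 0.519 to 66.7 (6.97 ± 1.57, adjusted p = 0.0168). The near-identical hsp-16.48 copies WBGene00002020 and WBGene00002019 rose by 6.34 and 6.28 (adjusted p = 0.0380 and 0.0407). The major sperm protein genes msp-76 and msp-79 (−7.01 and −6.95) and smz-1 (−6.42) fell, each at an adjusted p of 0.0375, and msp-77 (IV 9894631–9895014) was at least 43.4-fold lower (adjusted p = 0.0157). These were the 4 of 41 sperm genes that fell, 23 adjusted over the list alone (median −5.04, −3.25 with bounds; camera adjusted p = 6.0e-19, 0.470 with an estimated correlation), with nspd-1 at −5.08 (adjusted p = 0.105). Y102A11A.5 sense fell (−7.29 ± 1.57, adjusted p = 0.00976), and Y37A1B.7, linc-17 and mir-43 were at least 52.3-, 44.1- and 38.4-fold lower (adjusted p = 0.0168, 0.0178 and 0.0375).

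Antisense rRNA reads stood higher in erh-2, with 0 of 23 past the test and 8 adjusted over the list alone (median 3.07, camera adjusted p = 1.0e-12, 0.392 with an estimated correlation); rrn-3.1 antisense stood at 4.27 ± 1.41 (adjusted p = 0.228). Of all assigned reads 0.0658% were antisense to rRNA in erh-2, 0.00491% in control, 0.0126% to 0.0459% in the tofu-6 alleles, 0.0216% in pics-1 and 0.0241% in prg-1. Mature piRNAs had 1 higher and 2 lower of 264, or 8 and 96 adjusted over the list alone (median −3.90, −2.82 with bounds; camera adjusted p = 7.2e-17, 0.392 with an estimated correlation). Named members were mature_piR-cel-4817 at −5.46 (adjusted p = 0.0704) and mature_piR-cel-3975 at −4.13 (adjusted p = 0.221). MicroRNA genes had 1 of 129 lower, or 30 adjusted over the list alone (median −2.60, 0.32 scaled to microRNA reads, camera adjusted p = 1.0e-19, 0.392 with an estimated correlation). In untreated erh-2 the microRNA share stood at 2.27 times control instead. Histone genes had 0 of 71 past the test sense on either adjustment (median −2.40, 0.52 scaled to microRNA reads; 1.1e-15, 0.392 with an estimated correlation; his-47 (WBGene00001921) at −2.32, adjusted p = 0.483). Somatic genes had 3 of 116 lower sense, or 14 adjusted over the list alone (median −1.51, 1.38 scaled to microRNA reads; 1.5e-07, 0.549 with an estimated correlation). Antisense reads at WAGO-class genes had a median of −0.87 (2.06 scaled to microRNA reads), with bath-45 at −0.87 (adjusted p = 0.725). By edgeR 2410 features had an unadjusted p under 0.05, and with DESeq2 size factors or without rRNA features 0 passed (2026 and 2110 unadjusted; the Wald test called 21, with 3 of the 13 named calls). Without it20 4 passed, without ust95 4 and without yt2 87. None of the 13 named calls remained without it20 or without ust95. Scaled to microRNA reads 5599 rose and 8 fell with a median of all features of 2.79.

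**Figure D3:**
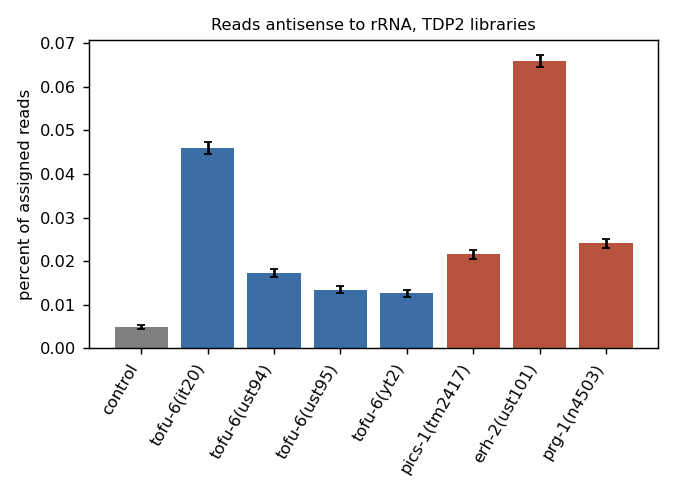
Reads antisense to rRNA genes are drawn as a percentage of assigned reads in each TDP2 library, with exact 95% intervals for counting error. The control lies lowest at 0.00491%, and erh-2 (0.0658%) and tofu-6 it20 (0.0459%) lie highest.

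In the prg-1 TDP2 library antisense small RNAs fell at a large set of protein-coding genes, and 57 of 264 mature piRNA features fell. Of 22372 features 20 rose and 1239 fell (median of all −0.11), and 1045 of the falls were antisense to protein-coding genes, 12.1% of the 8659 such features tested. That set went from 64645 CPM in control to 545 in prg-1, with no read left at 482 of its features, while all other antisense features of protein-coding genes went from 83763 to 70340. The set was picked by the same libraries, so its steep fall and the smaller change elsewhere partly follow from that choice. Antisense reads at F02E11.4 (II 3276041–3277786) were at least 685-fold lower (adjusted p = 5.9e-05), and those at C44C10.5, F46F2.4, unc-10 (X 7272317–7280322), a gene of synaptic vesicle release, and Y38H6C.10 at least 484-, 471-, 384- and 370-fold lower (adjusted p = 7.9e-05, 7.9e-05, 7.9e-05 and 8.0e-05). Of 9 WAGO-class genes 5 fell antisense, or 8 adjusted over the list alone (median −4.63, camera adjusted p = 2.2e-11, 0.366 with an estimated correlation). Among them bath-45 fell from 1206 to 3.17 CPM (−8.56 ± 1.77, adjusted p = 0.000214). F37D6.3 (−8.15 ± 1.74, adjusted p = 0.000326) and F15D4.5 (−4.63 ± 1.46, adjusted p = 0.0308; 0.0528 to 0.0677 with any 1 allele left out) fell too, while Y47H10A.5 stood at −3.39 (adjusted p = 0.175). Of 15 ERGO-1 26G targets 5 fell antisense, or 12 adjusted over the list alone (median −3.74, 1.9e-11, 0.366 with an estimated correlation). They included E01G4.5 (−6.38 ± 1.59, adjusted p = 0.00245) and W04B5.2 (−5.57 ± 1.52, adjusted p = 0.00716), which fell sense too (−5.92, adjusted p = 0.0282). Somatic genes had 8 of 34 lower antisense, or 16 lower and 1 higher adjusted over the list alone (median −4.32, −2.17 with bounds; 1.6e-08, 0.366 with an estimated correlation).

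Antisense reads on the germline and oocyte list and on the 22G pathway list did not share this loss in prg-1. Some genes outside these lists had far fewer than control, such as his-24 (2531 reads to 35) and parn-1 (1123 to 88). The piRNA pathway list, which holds parn-1, had an antisense median of −0.03. The germline and oocyte list had 0 of 30 past the test (median 0.00), with klp-7, a kinesin that acts on spindles, at −0.22. The 22G pathway list had 0 of 17 (median −0.42, 1.60 scaled to microRNA reads), with the Argonaute genes csr-1 at −0.46 and wago-4 at −0.06. The adjusted p was 1 for all 3, and klp-7 and wago-4 turned to 0.035 and 0.19 with DESeq2 size factors. Of 264 mature piRNA features 57 fell, or 131 lower and 2 higher adjusted over the list alone (median −7.03, −2.33 with bounds; camera adjusted p = 9.7e-19, 0.365 with an estimated correlation). No read was left of mature_piR-cel-3975 and mature_piR-cel-4817, at least 101.9- and 114-fold lower (adjusted p = 0.000165 each). Of 507 precursors 17 fell and 0 rose, the same adjusted over the list alone (median 0.52), with pre_piR-cel-18932 going from 106 to 0.151 CPM (−9.33 ± 1.90, adjusted p = 0.000182). The mature feature of that locus had 14 reads in control TDP2 and 0 in prg-1 TDP2. Whether the precursor reads there came from an overlapping gene was not tested. Of 129 microRNA genes 6 fell, or 4 adjusted over the list alone (median −1.44, 0.58 scaled to microRNA reads), mir-58 among them (−4.32 ± 1.44, adjusted p = 0.0494, and 0.126, 0.0782 and 0.1002 without ust94, ust95 and yt2). In untreated prg-1 the microRNA share stood at 1.51 times control instead. The rises included Y38C9A.1 antisense from 25.5 to 3448 CPM (7.08 ± 1.64, adjusted p = 0.000975), Y79H2A.4 sense (7.01 ± 1.65, adjusted p = 0.00123), and C38D9.2 sense (V 17567150–17571742; 5.24 ± 1.49, adjusted p = 0.0114). B0250.19 sense (5.13 ± 1.49, adjusted p = 0.0144) and T16G12.3 antisense (5.12 ± 1.42, adjusted p = 0.00906) rose too. Sperm genes had 0 of 41 past the test sense on either adjustment (median 1.80, 9.3e-13, 0.505 with an estimated correlation; nspd-1 at 2.14, adjusted p = 0.546). For rRNA genes 1 of 23 was higher antisense, or 0 adjusted over the list alone (median 3.24, 1.5e-16, 0.366 with an estimated correlation; rrn-3.1 at 2.62, adjusted p = 0.385). Histone genes had 0 of 71 past the test sense (median −0.18, 0.07 with DESeq2 size factors and 1.84 scaled to microRNA reads), with his-47 (WBGene00001921) at −0.77 (adjusted p = 1). With DESeq2 size factors 432 features passed, with rRNA features left out 617, without it20 665 and scaled to microRNA reads 8 (7 higher, 1 lower; median of all features 1.89, and 0.14 with DESeq2 size factors); 11, 15, 16 and 3 of the 20 named calls remained. By edgeR 2736 features had an unadjusted p under 0.05, and the Wald test called 1008, with 17 of the 20 named calls.

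**Figure D4:**
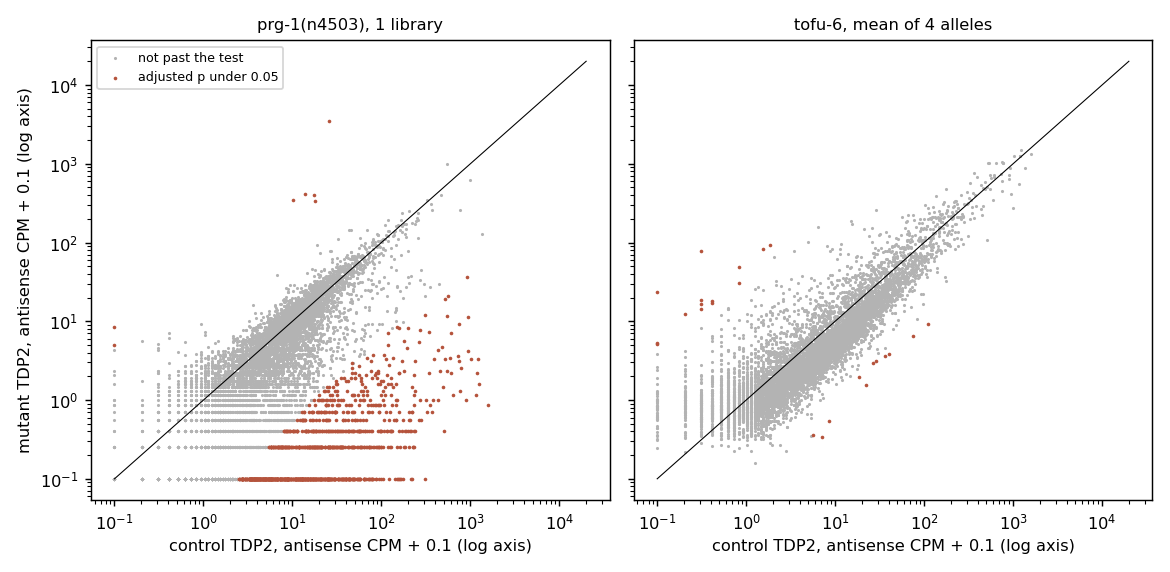
Each point is the antisense reads of a protein-coding gene in CPM plus 0.1, control TDP2 on the horizontal and mutant TDP2 on the vertical axis (both log scale), for the prg-1 library and for the mean of the 4 tofu-6 libraries, with features past an adjusted p of 0.05 in red. In prg-1 1045 features lie below control past the test and 7 above, and in tofu-6 11 below and 14 above.

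The tofu-6 and prg-1 TDP2 libraries were compared directly, to see which losses tofu-6 mutants did not share with prg-1. Antisense reads were higher in tofu-6 at 6 of 9 WAGO-class genes and 7 of 15 ERGO-1 26G targets, and sense reads were lower at 24 of 41 sperm and 15 of 71 histone genes. In all, 1438 features were higher and 171 lower of 22372 (median of all 0.52). The 1045 antisense features that fell in prg-1 had a median of −0.03 in tofu-6 against control (512 of them above 0), which turned to 0.04 with DESeq2 size factors and 1.75 scaled to microRNA reads. The other 7614 antisense features of protein-coding genes had −0.67 (1625 above 0), −0.61 and, turned, 1.08. The 1045 features were picked by values of the same control library. WAGO-class genes had 6 of 9 higher antisense, or 9 adjusted over the list alone (median 4.112, camera adjusted p = 8.8e-09, 0.451 with an estimated correlation). Among them bath-45 stood at 8.63 ± 1.72 (adjusted p = 7.2e-05), F37D6.3 at 8.40 ± 1.70 (adjusted p = 8.9e-05), F15D4.5 at 4.112 ± 1.33 (adjusted p = 0.0319) and K02E2.6 at 3.91 ± 1.31 (adjusted p = 0.0409). The F15D4.5 call was lost without it20 (3.84), ust94 (4.23) or ust95 (3.78), and the K02E2.6 call without it20 (4.10), ust95 (3.76) or yt2 (3.31). ERGO-1 26G targets had 7 of 15 higher antisense, or 11 adjusted over the list alone (median 3.38, 4.6e-08, 0.4998 with an estimated correlation), with E01G4.5 at 5.17 ± 1.42 (adjusted p = 0.00640). Somatic genes had 12 of 34 higher antisense, or 13 adjusted over the list alone (median 5.15, 2.25 with bounds; 4.0e-08, 0.487 with an estimated correlation). The GABA receptor gene unc-49 (III 10520762–10532705), Y38H6C.10, F22H10.4, pxd-1 and F46F2.4 had no antisense read in prg-1 and were at least 690-, 722-, 502-, 458- and 456-fold higher in tofu-6, above prg-1 in 4 of 4 alleles (adjusted p = 9.8e-06, 9.8e-06, 1.7e-05, 1.7e-05 and 1.7e-05).

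Sense reads of sperm genes were lower in tofu-6 than in prg-1 at 24 of 41 genes, or 35 adjusted over the list alone (median −3.09, camera adjusted p = 6.2e-44, 0.451 with an estimated correlation). The ust95 library stood apart, with 241 RPM over the list against 17.9 to 29.9 in the other alleles and 463 in prg-1. The genes included smz-1 (−3.90 ± 0.81, adjusted p = 0.000132), nspd-1 (−3.42 ± 0.80, adjusted p = 0.000708), nspd-6 (−3.37 ± 0.81, adjusted p = 0.00120) and msp-77 (−2.53 ± 0.83, adjusted p = 0.0341, and −4.07 antisense, adjusted p = 0.0484). Without it20 the sense calls of nspd-1 (−3.21), nspd-6 (−3.05) and msp-77 (−2.16) were lost, the last also without ust94 (−2.28), and without ust95 msp-77 stood at −4.76. Antisense msp-77 was lost without it20 (−4.03) or ust94 (−3.76). Histone genes were lower sense at 15 of 71, or 30 adjusted over the list alone (median −1.91, 2.8e-28, 0.451 with an estimated correlation), among them his-47 (WBGene00001931) at −2.91 ± 0.80 (adjusted p = 0.00649; 0.137 without it20). They were higher antisense at 14 of 70, or 25 higher and 1 lower adjusted over the list alone (median 1.93, 1.5e-05, 0.789 with an estimated correlation). The linker histone his-24 stood at 6.25 ± 1.52 (adjusted p = 0.00125) and the his-47 copies WBGene00001921 and WBGene00001931 at 6.28 and 5.16 (adjusted p = 0.000757 and 0.00415). At his-24 prg-1 had 35 antisense reads, control TDP2 2531 and the tofu-6 alleles 1636 to 5970. The yt2 library carried both his-47 values, and without it they were 2.57 and 2.42 (adjusted p = 0.164 and 0.157); with DESeq2 size factors the adjusted p was 0.330 and 0.313. Y38C9A.1 antisense (−7.29 ± 0.90, adjusted p = 8.4e-12), Y79H2A.4 sense (−6.51, adjusted p = 3.8e-09), fipr-20 sense (−5.90, adjusted p = 8.1e-07), F16B4.6 sense (−5.61, adjusted p = 3.6e-07) and T16G12.3 antisense (−5.54, adjusted p = 1.2e-07) were lower in every tofu-6 allele. Mature piRNAs had 18 higher and 2 lower of 264, or 19 and 2 adjusted over the list alone (median 4.83, 0.53 with bounds; 2.1e-05, 0.510 with an estimated correlation), mature_piR-cel-15879 being lower (−3.01, adjusted p = 0.00445). Precursors had 24 higher and 10 lower of 507 (23 and 10 adjusted over the list alone), with a median of 0.09 that turned to −0.16 with DESeq2 size factors, and pre_piR-cel-15748 was lower (−3.74 ± 0.80, adjusted p = 0.000180). Antisense reads at klp-7 stood at −0.60 (adjusted p = 0.814). With DESeq2 size factors 713 features passed, with rRNA features left out 954 and without it20 959 (17, 19 and 18 of the 26 named calls remained, and 22 by the Wald test). Scaled to microRNA reads 903 were higher and 158 lower, and the median of all features was 0.26 with DESeq2 size factors and 0.28 scaled to microRNA reads.

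Each untreated mutant was compared with the untreated control as 1 library against 1, so the values below are ratios with no test. Sense reads of histone genes were lower in tofu-6(ust94), pics-1, erh-2 and tost-1, and not by as much in prg-1. Together they held 1382 RPM in control, 191 in tofu-6(ust94), 201 in pics-1, 201 in erh-2, 210 in tost-1 and 943 in prg-1. At least 4-fold lower were 31 of 32, 31 of 33, 31 of 32 and 31 of 32 histone genes in the first 4 and 0 of 33 in prg-1 (medians −3.20, −3.11, −3.03, −2.96 and −0.60). Each list median lay below all 10000 random lists (percentile 0), with no direction turned by a scaling. Near-identical histone copies may share reads and move as 1, which makes that percentile easier to reach. The his-47 (WBGene00001921) ratios were 0.106, 0.115, 0.141, 0.124 and 0.793 and the his-64 ratios 0.0808, 0.102, 0.118, 0.131 and 0.626. Over all features with 100 reads, 210 of 4422 were at least 4-fold higher and 54 lower in tofu-6(ust94), 146 and 77 of 4100 in pics-1, 87 and 63 of 3206 in erh-2, 8 and 57 of 2326 in prg-1 and 1 and 48 of 2630 in tost-1. These splits depended on the scaling: per microRNA read they were 21 and 316, 26 and 205, 12 and 117, 4 and 68, and 1 and 47. With TMM 47.9%, 35.8%, 41.8%, 16.7% and 1.85% of the features changed at least 4-fold were higher, against 79.5%, 65.5%, 58.0%, 12.31% and 2.04% by assigned reads. The medians of all features were 0.80, 0.85, 0.68, −0.15 and 0.48, and per microRNA read −0.95, −0.52, −0.50, −0.75 and 0.51.

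In untreated tofu-6(ust94), pics-1 and erh-2 the highest ratios to control included single heat shock genes, which were not counted as a list. Sense reads of hsp-70 were at least 68.0-, 59.8- and 85.4-fold higher and those of hsp-16.41 at least 48.2-, 33.9- and 63.4-fold higher. The hsp-16.48 copy WBGene00002019 had 1 read in control and ratios of 180 (32.1 to 7137), 149 (26.5 to 5927) and 200.4 (35.6 to 7947). F56A8.9 sense had no read in control and was at least 293-, 163- and 65.1-fold higher in these 3 mutants and at least 99.1-fold higher in tost-1. In tofu-6(ust94) and pics-1 the nuclear receptor gene nhr-241 was at least 38.8- and 29.0-fold higher, and in erh-2 hsp-16.2 had a ratio of 159 (28.2 to 6311). Among the lowest ratios were his-45 (0.0685), his-2 (0.0744) and his-15 (WBGene00001885; 0.0750) in tofu-6(ust94), and his-9 (WBGene00001899; 0.0591), his-40 (0.0625) and his-17 (0.0670) in pics-1. Antisense reads at linc-12 had ratios of 0.0702, 0.0278 and 0.0223 in tofu-6(ust94), pics-1 and erh-2. In erh-2 the cuticle collagen dpy-14 (0.0391), the heterochronic gene hbl-1 (0.0578) and noah-1, an embryonic matrix gene (0.0601), were lowest sense.

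Summed antisense reads at protein-coding genes stood at 2.24 of control in untreated tofu-6(ust94), 1.77 in pics-1 and 1.32 in erh-2, which turned to 0.667, 0.686 and 0.582 per microRNA read. At WAGO-class genes the antisense medians were 2.72, 2.44 and 1.48 (percentiles 99.95, 100 and 97.8), or 0.97, 1.07 and 0.30 per microRNA read, over the 7, 4 and 4 genes with 100 reads. Genes could reach that minimum through the mutant library alone, which favours high ratios. Among these genes bath-45 had ratios of 6.65, 6.94 and 3.34, or 1.97, 2.69 and 1.47 per microRNA read. MicroRNA genes had medians of 1.77, 1.44, 1.14 and 0.84 in tofu-6(ust94), pics-1, erh-2 and prg-1 and 0.03 in tost-1. Per microRNA read, a scaling that holds their sum level, the erh-2 median was −0.04. The mir-58 ratios were 3.79, 2.82, 2.36, 1.84 and 1.18, those of let-7 3.01, 2.32, 1.86, 1.88 and 0.988, and those of mir-35 1.77, 1.30, 1.43, 0.693 and 0.710, which turned to 0.526, 0.504 and 0.630 per microRNA read in the first 3. Germline and oocyte genes had sense medians of 0.97, 0.93, 0.78, −0.43 and 0.81, which turned to −0.78, −0.44 and −0.40 per microRNA read in the first 3. In untreated prg-1 mature piRNAs had a median of −8.32 with 34 of 34 features at least 4-fold lower, and ERGO-1 26G targets had an antisense median of −3.59, with E01G4.5 at 0.0268. The 34 features reached the minimum of 100 reads through control, as untreated prg-1 held 241 mature piRNA reads in all. Their count was thus largely fixed by the filter. The ratio of all mature piRNA reads, 0.00589, needs no such minimum. Antisense reads at fbxb-37 (0.0188), Y116F11A.1 (0.0239), Y37E3.30 (0.0256) and linc-16 (0.0361) were the other lowest in prg-1. The highest prg-1 ratios were F15D4.5 sense (85.7, 15.1 to 3411, 1 control read), timm-17B.2 (18.5), Y38C9A.1 antisense (10.501), C49C8.1 antisense (7.18) and pud-2.2 (WBGene00017500; 5.89). In tost-1 the lowest were his-15 (WBGene00001889; 0.0748), his-15 (WBGene00001885; 0.0835), his-9 (WBGene00001899; 0.0859), F55C9.5 antisense (0.0884) and his-16 (0.0929), and after F56A8.9 the highest were ocrl-1 (3.18), the noncoding RNA rncs-1 (3.127), F54E2.1 (2.98) and clec-209 (WBGene00018910; 2.91).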

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

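The tests of the whole library's yield, the TDP2 step, a deletion, the amount of rRNA and the capture of antisense RNA were chosen only after the result was seen; the test of strand errors was written before its result. Each measure over the 4 tofu-6 TDP2 libraries was searched for a library far from the other 3, and 9 of 59 measures had one. Chance alone marks about 1 in 20 where measures are taken without regard to their values. Many of these were single features printed mostly because they passed the test, so that rate does not apply to them. The alleles are different strains, so genotype and handling are not separable here, and leaving out it20 alone took the tofu-6 count from 59 features to 4.

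The it20 library stood apart in antisense rRNA (0.0459% of assigned reads against 0.0126% to 0.0172%), snRNA (11.67% against 5.44% to 5.71%), transposon antisense reads (0.0652% against 0.000602% to 0.00527%) and pre_piR-cel-15748 (22.2 CPM against 6.48 to 7.84). The transposon antisense reads of the TDP2 libraries all lay at 1 feature, F44E2.2. The yt2 library stood apart in antisense reads at his-47 (WBGene00001921) with 309 CPM against 1.16 to 17.2, at his-47 (WBGene00001931) with 316 against 3.78 to 33.2, and at unc-87 with 313 against 0.726 to 0.929. The ust95 library stood apart in sense reads of the sperm genes msp-77 (16.1 against 0.464 to 2.03) and nspd-1 (34.7 against 2.27 to 6.62).

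Antisense rRNA reads made up a larger share in each of the 7 mutant TDP2 libraries than in the single control. More rRNA in the mutants is argued against, since antisense reads per sense rRNA read were at least 1.95 times control in every mutant (lowest in ust94, 1.76 to 2.17). A higher capture of all antisense RNA could not be excluded in every library: antisense rRNA reads per protein-coding antisense read were at least 1.5 times control, with the interval, in 6 of the 7, but 1.45 (1.29 to 1.62) in yt2. Protein-coding antisense reads lay under control in 4 of the 7 per assigned read and above it in all 7 per microRNA read (1.31 to 4.96). A higher rate of strand errors stays open too: the antisense share of microRNA reads was under 1.5 times control, with its interval, in 1 of the 7 libraries (ust95, 1.14), and it reached 4.48 in erh-2. With 1 control library, a low value in that library and a biological effect of the mutations cannot be told apart by these counts.

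The tofu-6 and prg-1 effects, each measured against the same control, differed in a direct edgeR test at 1609 features. Most of these were antisense reads lost in prg-1, a loss for which a lower yield of antisense RNA in that library is argued against: the lowest antisense median of the 22G pathway and germline lists over 3 scalings was −0.42. A failed TDP2 step in that library alone is argued against as well, for the 35 of 1045 lost genes with at least 20 reads in untreated control. Over these 35 the untreated prg-1 library had a median log2 ratio of −3.76, with 34 under −1. They were kept by their control reads, which can pull the ratio down, and the other lost genes were not covered. A deletion of a 22G pathway gene in the prg-1 strain stays open, the lowest sense ratio among 17 such genes being 0.290 at rde-2 (0.180 to 0.453, 27 and 81 reads). The loss of PRG-1 itself also stays open as a candidate explanation, and it was not tested apart from the strain.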

How the results depend on the processing

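Fits without features antisense to piRNA loci, fits without rRNA features, and shares over the 521 mature piRNA features with 10 reads in untreated control were chosen after seeing the data, and the other settings were planned. The cause of a change was not tested unless a sentence gives one. With 1 control TDP2 library, and with it20, ust94, ust95 and yt2 as the only replicates, calls for single features rest on the spread between alleles. That spread was pooled over features, so a feature's own spread had no weight in its call.

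Counted per microRNA read, mature piRNA ratios to untreated control were 0.207 in tofu-6(ust94), 0.116 in pics-1, 0.2501 in erh-2, 0.00390 in prg-1 and 1.51 in tost-1. In TDP2 libraries they were 1.17 in tofu-6 and 2.29 in erh-2, both reversed, 0.381 in pics-1 and 0.838 in prg-1. Pre-piRNA ratios were 4.75, 4.02, 12.7 and 5.66 in tofu-6, pics-1, erh-2 and prg-1, and antisense rRNA ratios 18.7, 9.78, 138 and 27.04. Among non-structural reads the untreated mature ratios were 0.321 in tofu-6(ust94), 0.159 in pics-1, 0.326 in erh-2 and 1.28 in tost-1. The TDP2 ratios of pics-1, erh-2 and prg-1 were then 0.139, 0.345 and 0.349 for mature piRNAs, 1.46, 1.91 and 2.36 for pre-piRNAs and 3.56, 20.8 and 11.3 for antisense rRNA. Over the 521 features the untreated ratios were 0.681 in tofu-6(ust94), 0.587 in erh-2, 0.00292 in prg-1 and 1.45 in tost-1, and the TDP2 ratios 0.0615 in pics-1, 0.0627 in erh-2 and 0.0177 in prg-1. Counted per microRNA read as well, they were 0.647 in erh-2 and 0.888, 0.684, 1.03 and 0.668 in it20, ust94, ust95 and yt2, so that the reversal held only in ust95. The 521 features were kept by their reads in control, which can pull ratios to control down. Leaving out an allele kept the tofu-6 ratios within 0.293 to 0.394 (mature piRNAs), 1.15 to 1.49 (pre-piRNAs) and 2.94 to 5.21 (antisense rRNA).

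Counts of changed features are given for tofu-6, pics-1, erh-2 and prg-1 against control and tofu-6 against prg-1, where the fit above called 59, 12, 38, 1259 and 1609. By edgeR with DESeq2 size factors they were 0, 0, 0, 432 and 713 (898, 652, 2026, 2279 and 3088 at an unadjusted p under 0.05), and without rRNA features 0, 0, 0, 617 and 954 (982, 740, 2110, 2326 and 3324 unadjusted). Scaled to microRNA reads they were 6, 5, 5607, 8 and 1061, a scaling that in the 4 contrasts against control moved the median of all features by more than any other setting run. The DESeq2 Wald test called 9 in tofu-6 and 21 in erh-2, the fit with no filter 21 in erh-2, and the fit without features antisense to piRNA loci 4 in pics-1 and 11 in erh-2. The fit of 10 libraries with genotype plus library type called 70 in tofu-6, 75 in pics-1, 77 in erh-2 and 844 in prg-1. Of these, 4, 6, 19 and 683 were among the features called by the fit above, so similar counts did not mean the same features. Leaving out 1 allele gave 4 to 101, 2 to 45, 4 to 87, 665 to 1465 and 959 to 1907. With an estimated correlation camera called 0 of 27 lists in each of the 5 contrasts. For the effect of TDP2 every setting stayed within 1.5 times the 11994 features called, from 9663 without the pics-1 pair to 13788 scaled to microRNA reads; without the strain block that pairs the libraries it was 11317. Untreated features changed at least 4-fold numbered 142 in tofu-6(ust94) with TMM, and with a minimum of 20 reads 870, 863, 507, 547 and 212 in tofu-6(ust94), pics-1, erh-2, prg-1 and tost-1, since more features were counted.

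Of the features named in the TDP2 contrasts, 114 features under 12 settings gave 1336 values, of which 987 kept their direction and side of the threshold, 308 lost the call, 10 gained it and 31 changed direction. A feature to which the Wald test gave no adjusted p counts as not past the threshold. The 628 features the naming rule covers gave 7300 values, of which 6514 stayed, 308 lost the call, 66 gained it and 412 changed direction, 2 of them from a called value. Scaled to microRNA reads the reversed log2 values were 1.63 for tofu-6 sense and 0.36 for E01G4.5 antisense in tofu-6, and 0.60 for his-47 (WBGene00001921) sense and 2.06 for bath-45 antisense in erh-2. In prg-1 they were 1.26 for his-47 (WBGene00001921) sense, 1.60 for prg-1 sense, 0.88 for prg-1 antisense, 1.81 for klp-7, 1.57 for csr-1 and 1.96 for wago-4 antisense. Antisense reads of klp-7 and wago-4 in prg-1 also turned with DESeq2 size factors (0.035 and 0.19), the Wald test (0.035 and 0.19), no rRNA features (0.12 and 0.27), no filter (0.061 and 0.22), 10 libraries (0.16 and 0.11) and without yt2 (0.11 and 0.27; with all leave-one-outs −0.21 to 0.11 and −0.057 to 0.27). In tofu-6 the fit of 10 libraries, which has ust94 as its only tofu-6 allele, reversed the called his-47 (WBGene00001921) antisense (−0.59) and his-12 (WBGene00001886) antisense (−0.11), and pre_piR-cel-18932 (−0.33) and tofu-6 antisense (−3.34). Leaving out 1 allele gave −0.78 to 0.020 for tofu-6 sense (reversed without ust94), −0.37 to 0.30 for bath-45 antisense (without yt2, and −0.036 without ust95), −0.33 to 0.35 for pre_piR-cel-18932 and −0.61 to 1.10 for tofu-6 antisense (both without yt2). Of 188 values for 19 features named for the effect of TDP2, 185 stayed and 3 lost the call. Of 762 values for 381 untreated features, 581 moved beyond their counting interval and 181 did not.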

Other observations

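The tests of the scaling and of histone copies below and the comparison with other splits were chosen only after the result was seen; the test of embryo transcripts was written before its result. Some classes not described so far also differed between strains. In the prg-1 TDP2 library 14 of 59 features antisense to lincRNA genes fell and 0 rose, and 15 of these 59 were higher in tofu-6 than in prg-1 with 0 lower. Of 531 tRNA features 22 were lower in tofu-6 than in prg-1 and 0 higher. Among features antisense to precursor piRNA loci, 5 rose and 3 fell of 78 in tofu-6, 3 and 2 in pics-1, 5 and 3 in erh-2 and 5 and 10 in prg-1.

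As shares of assigned reads, snRNA in the TDP2 libraries stood at 2.89 times control in erh-2 (2.88 to 2.90) and 3.86 times in prg-1 (3.85 to 3.88), 2.06 times in it20 and 0.962 to 1.16 times in the other 4 mutant libraries. Per microRNA read erh-2 and prg-1 stood at 29.8 and 21.3 times control, and among non-structural reads at 4.49 and 8.88 times, so the size and order depend on the denominator. Protein-coding antisense reads made up 15.5% of assigned reads in control TDP2, 10.9%, 5.01%, 15.7% and 27.5% in it20, ust94, ust95 and yt2, 28.7% in pics-1, 7.45% in erh-2 and 5.48% in prg-1. Only 1 antisense feature of the transposon class passed the filter, F44E2.2, and it held all such reads in the TDP2 libraries. The values below therefore cannot speak for transposons as a class. Untreated libraries had few reads antisense to transposon features, 4 in control against 94 in tofu-6(ust94), a ratio of 14.1 (5.33 to 52.9), 55 in pics-1 (9.21, 3.40 to 35.0) and 46 in erh-2 (9.72, 3.55 to 37.2). Per microRNA read these ratios were 4.1903, 3.57 and 4.29, and prg-1 and tost-1 had 12 reads each (2.09, 0.633 to 8.89, and 3.07, 0.929 to 13.04). In the TDP2 libraries the ratios to control (306 reads) went both ways: 19.8, 0.183, 0.821 and 1.60 in it20, ust94, ust95 and yt2, 2.73 in pics-1, 0.562 in erh-2 and 0.688 in prg-1. Per microRNA read they were 101.4, 0.742, 1.67, 4.44, 6.08, 5.80 and 3.79, so that ust95, erh-2 and prg-1 turned.

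Sense reads of histone genes in untreated tofu-6(ust94), pics-1, erh-2 and tost-1 stood far below control. The scaling is argued against as the cause, since the highest list median over these 4 mutants and 3 scalings was −2.93. Reads moving between near-identical copies are argued against, because the summed reads of all copies reached at most 0.152 of control, against 0.682 in prg-1. Fewer embryos in the mutant animals could not be excluded: 26 embryo genes together stood at 0.327 (erh-2) to 0.463 (pics-1) of control, between the bounds set in advance, with noah-2 at 18.7 RPM in control and 3.40, 2.56, 1.20 and 3.61 in these mutants. In prg-1 the embryo genes stood at 0.460 too, and an effect of the mutations on histone RNA itself stays open. Sense reads of sperm genes were lower as well, at 18.2, 5.40, 2.63 and 3.18 RPM in tofu-6(ust94), pics-1, erh-2 and tost-1 against 30.97 in control and 84.9 in prg-1, so a different make-up of germ cells also stays open.

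For the effect of TDP2, the libraries are paired by strain, and only 16 of the 126 splits of its 10 libraries into 5 and 5 part every pair, too few for a share under 0.05. The real split called 11994 features and the other 15 at most 0 by edgeR. Each of those 15 swaps the labels of some strains, which puts the TDP2 difference into the residual spread. Of the splits that keep some pairs together 87 were drawn, and they called at most 4346. These splits can still part other pairs by TDP2. Neither count therefore estimates how many features chance would call.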
